A study of Rattus norvegicus with 12 samples.

How the data were processed

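Each of the 12 arrays held 45018 spots, of which 43379 were not control spots and stood for 41012 probes; 263 probes were spotted more than once. Per the file headers, signals were extracted with Agilent Feature Extraction 9.1.3.1 in a single colour, with local background subtraction and spatial detrending and without scaling between arrays. Per the file headers, the processed signal, the mean signal and the background signal are linear intensities, and the columns that mark a spot as well above background, saturated or an outlier are flags of 0 or 1. The deposited value table of the authors is a linear ratio: the processed signal, with values under 5 set to 5, divided by 1 constant per array near that array's median. All 40749 probes spotted once lay within 0.1% of that rule on every array, with constants from 58.91 to 68.47. Its column medians ran from 1.003 to 1.005, so scale, centring and direction are known: linear, centred per array but not per gene, higher meaning more signal. The value table had 12 columns, 0 of them unused, and 41012 probe names matched it.

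The main values were log2 processed signals, averaged over the spots of a probe with outlier spots left out, minus the 75th percentile of the array. Probes were named through the accession in the array file (10735 probes), a current symbol (5571) or an older symbol (3729); 20977 had no match in the reference gene table and were kept under the name in the array file. The probe with the highest mean over the 12 arrays, chosen without the groups, stood for each gene, provided that at least 2 arrays of every group carried an unmarked spot. That left 35537 genes or unmatched transcripts. Of these, 20760 were well above background on all 3 arrays of at least 1 group and were tested; 11042 of them had a reference symbol, 11028 could be named and 19331 were well above background on all 12 arrays. In all, 24728 probes passed the same filter, and 3824 tested genes had more than 1 probe.

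Groups were compared with limma 3.58.1 in R 4.3.3, with 1 mean per group fitted to all 12 arrays, default empirical Bayes moderation and 8 residual degrees of freedom. All tests of genes and lists were two-sided, and a gene or list was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. Errors printed beside log2 changes are limma standard errors with n = 3 animals per group; their number limits the precision. Fold changes come from the same fit. Where a group's arrays were not well above background, the fold change is a bound, taken against the lowest normalized signal among probes well above background on each array, and is written as at least that many fold.

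Gene lists were tested with camera from limma, with the preset correlation of 0.01 between genes, and again with the correlation estimated from the data. There were 18 functional lists and 15 lists of cell type markers, written before the data were examined; 29 had at least 4 measured members and were tested. Not tested for want of members were the lists for neutrophils, B cells, red blood cells and the adrenal gland. Counts of members that rose or fell are given over all tested genes and adjusted over the list alone. Medians of lists take every measured member with its fitted value, unless said to be with bounds.

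The groups, the scaling, the filter, the probe choice, the lists, the tests and the alternatives to each were chosen before the data were examined. So was the rule for genes to be named: at each dose against control, the 10 higher and 10 lower genes with the largest change among those called, nameable and with the groups not overlapping; 5 and 5 between neighbouring doses; 2 up and 2 down per list; and a set of genes fixed in advance. Members of a list named beyond that rule, and gene families, were chosen after the values were seen. What each explanation of a pattern predicts was written before the tests were run, and for some explanations only after the result was seen. Added after the data were seen were the slide as a block with a 2-fold limit, quantile scaling with the slide as a block, the use of slides 2 and 3 alone for the same-sign share, and the correlation between doses under each setting.

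Alternatives tried for the values were quantile normalization, a median shift, normexp background correction of the mean signal with an offset of 50, and the authors' value table. For the probes they were no filter on dim probes, only probes well above background on all arrays, every probe on its own, and the mean of a gene's probes. For the fit they were only the compared groups, the replicate number as a block, trended and robust moderation, array weights, and the slide or the scan day as a block. A limit of 2-fold and leaving out each array in turn were also tried. Slides were read from the file headers. Slide 1 carried controls 1 to 3 and low 1; slide 2 carried low 2 and middle 1; slide 3 carried low 3 and middle 2; slide 4 carried middle 3 and high 1 to 3. Slide 2 was scanned on a day of its own. With slide as a block, low against control rests on low 1 minus the controls and high against middle on the high arrays minus middle 3, with 5 residual degrees of freedom. High against control is then a chain over all 4 slides, since these groups never shared a slide.

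The exact tests regrouped the 6 arrays of a comparison in all 10 ways into 3 and 3, so no share could go under 0.1; for the same-sign share, planned as one-sided, splits were counted in either direction. Correlations between doses that share controls were set against 100 simulated sets of groups with no effect at any dose. In a self-test, 200 genes of 20715 were changed on the high against control arrays: 76%, 94%, 96% and 98% were recovered at 1.5-, 2-, 3- and 4-fold, with 9 false calls. A simulated slide effect with a standard deviation of 0.15, a set value not estimated from the arrays, gave 1622 false calls without a block. With slide as a block it gave 5 false calls, and recovery fell to 10%, 36%, 64% and 78%. Other tools were the package data.table, version 1.17.8, and matplotlib 3.10.9 in Python 3.11.15 for figures.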

Results

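Kidney cortex of male Fischer rats was profiled 24 h after a single intravenous dose of cephaloridine, a cephalosporin antibiotic that damages the proximal tubule. The labels give 4 groups of 3 animals: control (0 mg/kg), low (150 mg/kg), middle (300 mg/kg) and high (600 mg/kg), with 1 array per animal. The stated purpose was to compare expression at subtoxic and toxic doses. The 12 arrays were alike in signal: medians ran from 65.1 to 74.8, 75th percentiles from 677 to 774, and 59.2% to 63.2% of probes were well above background, with 0 saturated spots. Controls and high-dose animals never shared a slide, so a difference between slides cannot be told from a dose effect for small changes. Values with slide as a block stand beside the results for this reason. Each blocked value against control starts from low 1 minus the controls, so from a single dosed array. Those at 300 and 600 mg/kg add the average of middle 1 minus low 2 and middle 2 minus low 3. The value at 600 mg/kg further adds the high animals minus middle 3, again a single array of its group. All share arrays with the calls. At 600 mg/kg against control the median standard error was 0.154 with slide as a block and 0.076 without, so a call lost with the block need not mean a smaller change.

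At 600 mg/kg the stress-inducible chaperone gene Hspa1a rose by 5.72 on the log2 scale (52.6-fold, standard error 0.28, n = 3 animals per group, adjusted p = 1.56e-06). Its near-identical neighbour Hspa1b, not well above background in controls, rose at least 24.4-fold (adjusted p = 7.03e-07), and the cochaperone gene Hsph1 rose 6.01-fold (log2 2.59 ± 0.13, adjusted p = 1.56e-06). Hmox1, the heme-degrading enzyme, rose 11.4-fold (log2 3.51 ± 0.11, adjusted p = 2.4e-07). The glucuronosyltransferase gene Ugt2b7 rose 38.4-fold (log2 5.26 ± 0.21, adjusted p = 6.09e-07). The conjugate exporter Abcc2 of the brush border rose 7.98-fold (log2 3.00 ± 0.11, adjusted p = 5.28e-07). Paralogs such as Hspa1a and Hspa1b, or members of the glucuronosyltransferase and glutathione transferase families, can share sequence, so the signal of 1 can hold some of the other. All 6 kept their call with slide as a block, with adjusted p = 0.00366 for Hspa1a (log2 4.97), 0.0152 for Hspa1b, 0.0101 for Hsph1, 0.00491 for Hmox1, 0.00868 for Ugt2b7 and 0.00366 for Abcc2.

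Other large rises took in the apolipoprotein gene Apoa4 (5.16-fold, log2 2.37 ± 0.10, adjusted p = 7.03e-07) and the lipase inhibitor Angptl4 (5.19-fold, log2 2.38 ± 0.17, adjusted p = 1.52e-05). The replication licensing gene Cdc6 rose 4.96-fold (log2 2.31 ± 0.07, adjusted p = 2.4e-07). Ccne1, the cyclin of S-phase entry, rose 4.67-fold (adjusted p = 4.59e-06), the quinone reductase Nqo1 4.59-fold (adjusted p = 6.09e-07) and the lysosomal glycoprotein gene Gpnmb 4.59-fold (adjusted p = 1.93e-06). The stromelysin gene Mmp3 rose at least 4.24-fold and the endothelial adhesion gene Sele at least 12.4-fold, with controls not well above background (adjusted p = 4.13e-06 and 4.42e-05). The last 2 had adjusted p = 0.0301 and 0.0489 with slide as a block, and Apoa4, Angptl4, Cdc6, Ccne1, Nqo1 and Gpnmb had 0.00366, 0.0194, 0.00395, 0.0273, 0.00951 and 0.0152.

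Genes used as readings of tubular injury moved too. Havcr1, the kidney injury molecule, rose 9.11-fold (log2 3.19 ± 0.51, adjusted p = 0.00123; log2 2.16, adjusted p = 0.278 with slide as a block). Its blocked value runs through low 3, which stood apart (log2 signal -1.86, against -3.87 and -4.05 on low 1 and low 2). Timp1, a metalloproteinase inhibitor, rose 2.42-fold (log2 1.27 ± 0.08, adjusted p = 9.05e-06; 0.0372 with slide as a block). Lcn2, an iron-carrier gene of injured tubules, rose at least 1.76-fold (adjusted p = 0.0159), a call lost without control 3 (adjusted p = 0.0578) and with slide as a block (adjusted p = 0.852, log2 0.21). Spp1 did not pass (log2 0.45, adjusted p = 0.131; log2 -0.70, adjusted p = 0.225 with slide as a block), nor did Clu (log2 0.22, adjusted p = 0.182; log2 0.00, adjusted p = 0.994 with slide as a block). Nor did the tubular protein Umod (log2 0.08, adjusted p = 0.265) or the metallothionein Mt1 (log2 -0.235, adjusted p = 0.366). The blocked values of Lcn2, Spp1 and Clu also run through low 3, which lay highest of the low animals (log2 signal -3.74, 5.77 and 2.76). Low 1 lay at -5.42, 4.79 and 2.23, and low 2 at -4.85, 5.25 and 2.24.

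Among genes that fell at 600 mg/kg, the male-pattern steroid hydroxylase Cyp2c11 fell by 2.37 on the log2 scale (5.16-fold, standard error 0.25, n = 3, adjusted p = 0.000127; log2 -3.71, adjusted p = 0.0125 with slide as a block). The peroxisomal and mitochondrial membrane gene Mpv17l fell by 0.97 (adjusted p = 1.88e-06; 0.0215 with slide as a block). The phosphate carrier Slc34a1 of the brush border fell 1.5-fold (log2 -0.59 ± 0.05, adjusted p = 2.67e-05; 0.0455 with slide as a block). The organic cation carrier Slc22a2 fell 1.6-fold (log2 -0.68 ± 0.08, adjusted p = 0.000331; log2 -1.09, adjusted p = 0.0218 with slide as a block). The glucose-releasing enzyme G6pc1 fell 1.89-fold (log2 -0.92 ± 0.09, adjusted p = 8.07e-05), a fall as large with slide as a block but not past there (log2 -0.95, adjusted p = 0.0586). Calls were also lost with slide as a block for the brush-border peptidase Folh1 (2.63-fold lower, adjusted p = 0.000145; log2 -0.69, adjusted p = 0.174 blocked by slide) and the pentraxin Apcs (2.66-fold lower, adjusted p = 2.23e-05; log2 -1.18, adjusted p = 0.0629 blocked by slide). The organic anion carriers Slc22a6 and Slc22a8, which take cephaloridine into the tubule cell, fell by 0.45 and 0.53 (adjusted p = 0.00697 and 0.00247), and with slide as a block by 0.32 and 0.15 without passing (adjusted p = 0.48 and 0.664).

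In all, 7224 of 20760 genes were called at 600 mg/kg (34.8%), 3732 higher and 3492 lower. At least 2-fold changes were seen in 352 of them, 268 higher and 84 lower. Most changes were small: the median size among called genes was 0.333 on the log2 scale, and in 56% of tested genes the 3 high arrays did not overlap the 3 controls, where chance gives 10%. With slide as a block 584 genes were called, 380 higher and 204 lower, 398 of them in both fits, and 130 of the 352 genes past 2-fold were kept. The sign was kept in 92.9% of the 7224, though both fits share arrays and no share without a dose effect was computed. The simulated slide effect gave 1622 false calls without a block, but its standard deviation of 0.15 was a set value. The low and middle groups, each on 3 slides, had median standard deviations between animals of 0.073 and 0.11, against 0.066 for controls. The 1622 is thus no estimate of false calls here, and how many small changes come from slide stays open.

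**Figure D1:**
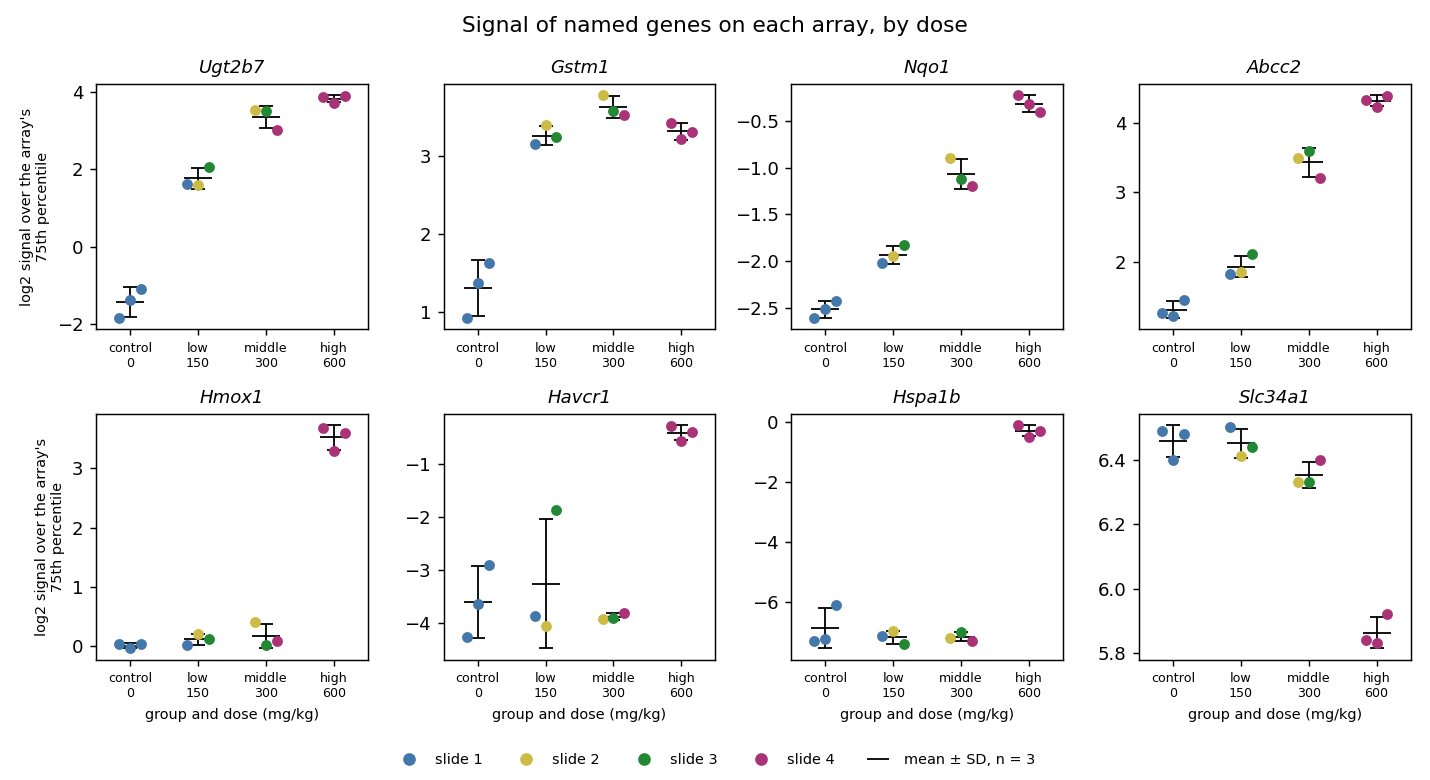
Signal of 8 genes on each array over the array's 75th percentile (log2), coloured by slide, with the mean and standard deviation of each group (n = 3). Ugt2b7, Gstm1 and Nqo1 were called higher at all 3 doses and Abcc2 at 300 and 600 mg/kg, whereas Hmox1, Havcr1 and Hspa1b were called at 600 mg/kg only.

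As groups at 600 mg/kg, heat shock genes moved in a single direction: of 16 measured, 12 rose and 0 fell (13 and 0 adjusted over the list alone), with a median of 0.448 (camera, adjusted p = 1e-07). That was adjusted p = 0.155 with an estimated correlation and 1.31e-06 with slide as a block. Of 27 glutathione and NRF2 target genes, 17 rose and 2 fell (17 and 2 adjusted over the list alone), with a median of 0.412 (adjusted p = 3.9e-08, adjusted p = 0.124 with an estimated correlation, 3.6e-06 with slide as a block). Among its members Nqo1, Gstm1 (4.02-fold, adjusted p = 2.3e-05) and the sulfiredoxin Srxn1 (5.57-fold, adjusted p = 6.88e-06) rose, while Gsta4 and Aldh1a1 fell. The subunits of glutamate-cysteine ligase, Gclc and Gclm, did not pass (log2 0.07 and 0.45, adjusted p = 0.547 and 0.0995), and Gclc turned to -0.43 with slide as a block (adjusted p = 0.0827). The fall of Gsta4 was lost without any of control 1, 2, 3 or high 1, 2, 3 (highest adjusted p = 0.083). Of 23 tubular injury markers, 15 rose and 0 fell (15 and 0 adjusted over the list alone), with a median of 0.447 (adjusted p = 9.05e-07, adjusted p = 0.155 with an estimated correlation). That median was 0.213 with slide as a block (adjusted p = 0.0289). Far fewer members were called with slide as a block: 4 of the 12 heat shock genes, 6 of the 17 NRF2 targets with 0 falling, and 3 of the 15 injury markers.

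Of 29 genes of inflammation and chemokines, 23 rose and 2 fell (24 and 2 adjusted over the list alone), with a median of 1.168, or 0.937 with bounds (adjusted p = 7.9e-08, adjusted p = 0.227 with an estimated correlation, 0.00024 with slide as a block). The monocyte attractants Ccl3 (6.03-fold, log2 2.59 ± 0.53, adjusted p = 0.00441) and Ccl7 (5.43-fold, log2 2.44 ± 0.58, adjusted p = 0.00924) rose, both lost with slide as a block (log2 1.03, adjusted p = 0.38 for Ccl3; log2 3.13, adjusted p = 0.179 for Ccl7). The neutrophil attractant Cxcl1 rose 6.62-fold (adjusted p = 0.0172), lost without control 1, control 3 or high 1 (highest adjusted p = 0.0652) and with slide as a block (log2 1.53, adjusted p = 0.603). The blocked value of Ccl3 runs through low 2 and low 3, which stood apart (log2 signal 1.61 and 1.26, against -0.78 on low 1). That of Cxcl1 runs through the same arrays (1.29 and -0.6, against -1.72 on low 1). Among 11 macrophage markers 8 rose and 0 fell (8 and 0 adjusted over the list alone), with a median of 0.265 (adjusted p = 0.000585, adjusted p = 0.258 with an estimated correlation, 0.0132 with slide as a block). Adgre1 led them (1.84-fold, adjusted p = 3.7e-05; log2 0.70, adjusted p = 0.0587 with slide as a block). Called with slide as a block were 3 inflammation genes, all higher, and 0 macrophage markers.

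Genes of the cell cycle rose in 21 of 37 and fell in 0 (24 and 2 adjusted over the list alone), with a median of 0.5 (adjusted p = 4.21e-09, adjusted p = 0.258 with an estimated correlation). The median was 0.802 with slide as a block (adjusted p = 1.54e-13). Besides Cdc6 and Ccne1 the replication helicase genes Mcm5, Mcm3 and Mcm6, picked after the values were seen, rose by 1.79, 1.73 and 1.71. Ribosomal protein genes rose in 28 of 36 with 0 falling (32 and 0 adjusted over the list alone, median 0.273, adjusted p = 2.03e-11, adjusted p = 0.257 with an estimated correlation, 4.96e-08 with slide as a block), Rps19 by 0.50. Proteasome genes rose in 13 of 27 with 0 falling (13 and 0 adjusted over the list alone, median 0.136, adjusted p = 3.48e-05, adjusted p = 0.282 with an estimated correlation, 0.00159 with slide as a block), Psmb7 by 0.37. Genes of metal and iron handling rose in 6 of 14 with 0 falling (7 and 0 adjusted over the list alone, median 0.243, adjusted p = 0.00276, adjusted p = 0.124 with an estimated correlation, 0.000556 with slide as a block). Among them were Hmox1 and the transferrin receptor Tfrc (2.27-fold, adjusted p = 9.58e-05). Members called with slide as a block, all higher, numbered 9 for the cell cycle, 1 for ribosomal proteins, 0 for the proteasome (Psmb7 log2 0.32, adjusted p = 0.187) and 2 for metal handling. Rps19 missed the threshold with a change as large (log2 0.54, adjusted p = 0.0656), while Tfrc was kept (adjusted p = 0.0278).

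Transporters of the proximal tubule mostly fell: 25 of 34 fell and 4 rose (25 and 5 adjusted over the list alone), with a median of -0.405 (adjusted p = 4.36e-06, adjusted p = 0.181 with an estimated correlation, 0.000647 with slide as a block). Against the trend of Slc34a1, Slc22a2, Slc34a3 and Slc7a7, the members Abcc2, Slc17a1, Slc17a3 and Slc22a12 rose. Genes of proximal tubule metabolism fell in 23 of 35 and rose in 2 (25 and 2 adjusted over the list alone), with a median of -0.295 (adjusted p = 4.21e-09, adjusted p = 0.124 with an estimated correlation, 1.31e-06 with slide as a block). Here G6pc1 and Pck1, both of glucose synthesis, fell, and Cyp24a1, which breaks down vitamin D, rose 3.65-fold (log2 1.87 ± 0.46, adjusted p = 0.0111; log2 3.7, adjusted p = 0.0588 with slide as a block), as did Rbp4. The rise of Rbp4 was lost without control 2, control 3, high 1 or high 2 (highest adjusted p = 0.104). Fatty acid oxidation and PPARA targets fell in 14 of 29 and rose in 3 (16 and 4 adjusted over the list alone, median -0.162, adjusted p = 0.00203, adjusted p = 0.288 with an estimated correlation, 0.754 with slide as a block). Ehhadh fell, and Angptl4, Cpt1a and Slc25a20 rose. Most of these calls were lost with slide as a block, which called 5 transporters lower and 2 higher, 1 metabolism gene lower and 0 higher, and 0 fatty acid genes lower and 1 higher. Ehhadh was lost (log2 -0.35, adjusted p = 0.21), as were Cpt1a (log2 0.29, adjusted p = 0.236) and Slc25a20 (log2 0.26, adjusted p = 0.156).

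Several functional lists moved weakly or in both directions at 600 mg/kg. Of 24 ER stress and ATF4 targets 8 rose and 10 fell (8 and 10 adjusted over the list alone). The median of -0.067 and the mean of 0.194 differed in sign, and the list did not pass (camera direction down, adjusted p = 0.951). Among those that rose were Atf3 (4.34-fold, adjusted p = 0.00255; log2 0.64, adjusted p = 0.448 with slide as a block), Chac1 (3.98-fold, adjusted p = 7.14e-05; log2 1.17, adjusted p = 0.07 with slide as a block), Trib3 and Asns. The blocked value of Atf3 runs through low 2 and low 3, which stood apart (log2 signal 1.54 and 1.7, against -0.05 on low 1). The ER chaperones Hspa5, Hsp90b1 and Pdia4 fell, as did Ddit4. Cholesterol synthesis genes rose in 15 of 24 with 0 falling (16 and 1 adjusted over the list alone, median 0.288, adjusted p = 3.73e-05, adjusted p = 0.258 with an estimated correlation, 0.0763 with slide as a block), Dhcr7 by 0.67. Of 17 p53 targets 9 rose and 1 fell (9 and 1 adjusted over the list alone, median 0.198, adjusted p = 0.0156, adjusted p = 0.227 with an estimated correlation, 0.754 with slide as a block, median 0.019). The cell cycle brake Cdkn1a in that list rose by 0.91 (adjusted p = 0.00843; log2 -0.05 with slide as a block). Its blocked value runs through the low animals, which differed (log2 signal -0.9 on low 1, against -0.22 and -0.15 on low 2 and low 3). The brightest probe of Mdm2 did not pass (log2 -0.03, adjusted p = 0.823). The other probe of Mdm2 did pass, with a rise of 0.39 (adjusted p = 0.00252), as did the mean of its probes (0.18, adjusted p = 0.0204), so its direction is not settled. Of 39 genes of oxidative phosphorylation and the citrate cycle 9 fell and 2 rose (8 and 1 adjusted over the list alone, median -0.102, adjusted p = 0.00482, adjusted p = 0.547 with an estimated correlation). That call was lost without control 3 (adjusted p = 0.0611), and with slide as a block the median turned to 0.03 (adjusted p = 0.865). Slide as a block called 1 ER stress gene higher and 0 lower, so the chaperones and Ddit4 lost their calls, which need not mean smaller falls. It called 0 cholesterol genes (Dhcr7 log2 0.38, adjusted p = 0.211), 0 p53 targets higher and 2 lower, and 0 genes of oxidative phosphorylation.

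Immediate early genes rose in 5 of 23 and fell in 1 at 600 mg/kg (5 and 1 adjusted over the list alone, median 0.468, adjusted p = 0.0202, adjusted p = 0.578 with an estimated correlation). The AP-1 member Fosl1 rose at least 4.99-fold (adjusted p = 0.000562; 0.0439 with slide as a block). The list of immediate early and AP-1 genes was lost without control 3 (adjusted p = 0.088) and with only probes well above background on all arrays (adjusted p = 0.0643), and with slide as a block it turned to a median of -0.549 (adjusted p = 0.00024). That blocked median runs through low 2 and low 3, which stood apart (0.84 and 0.54 over the controls, against -0.11 for low 1). Of 28 matrix and tissue repair genes 5 rose and 3 fell (5 and 3 adjusted over the list alone, median 0.074, adjusted p = 0.169): Mmp3, Mmp12 and Tgfb1 rose, and Ccn2, Mmp9 and Sparc fell. The fall of Ccn2 was lost without high 1 (adjusted p = 0.0507). Of 12 reference genes 4 rose and 1 fell (4 and 1 adjusted over the list alone, median 0.08, adjusted p = 0.11). Actb did not pass (log2 0.13, adjusted p = 0.123), while Gapdh and Hprt1 were among those that rose. Gapdh was lost without control 1, control 2, high 2 or high 3 (highest adjusted p = 0.0864), and Hprt1 without control 1, control 2 or high 3 (0.0689). Slide as a block called 1 immediate early gene higher and 2 lower, and 1 matrix gene each way.

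Markers of other cell types at 600 mg/kg fell for endothelium, 7 of 12 with 0 rising (8 and 0 adjusted over the list alone, median -0.249, adjusted p = 0.000585, adjusted p = 0.227 with an estimated correlation, 0.000647 with slide as a block). All 5 markers of the distal convoluted tubule rose (5 adjusted over the list alone, median 0.316, adjusted p = 0.00647, adjusted p = 0.266 with an estimated correlation, 0.000343 with slide as a block). The calcium-binding Calb1 rose by 0.69 (adjusted p = 0.00535; log2 1.31 with slide as a block). Of its 3 other probes 2 had the same sign, up to 0.68, and 1 did not (-0.08, adjusted p = 0.576). Intercalated cell markers rose in 5 of 8 with 0 falling (6 and 0 adjusted over the list alone, median 0.257, adjusted p = 0.00173, adjusted p = 0.266 with an estimated correlation, 6.06e-05 with slide as a block). The ammonia channel Rhcg rose by 0.62 (adjusted p = 8.79e-05). Loop of Henle markers rose in 1 of 7 (1 adjusted over the list alone, median 0.197, adjusted p = 0.0302, adjusted p = 0.258 with an estimated correlation, 0.109 with slide as a block). That call was lost without control 2 (adjusted p = 0.0583) or high 2 (adjusted p = 0.0518). Fat tissue markers rose in 3 of 5 (4 adjusted over the list alone, median 0.36, adjusted p = 0.0391, adjusted p = 0.258 with an estimated correlation, 0.865 with slide as a block, median 0.014). It was lost without control 3 (adjusted p = 0.0692), middle 2 (adjusted p = 0.0555) or high 2 (adjusted p = 0.0657), and with array weights (adjusted p = 0.0635). Slide as a block called 0 endothelial, 2 distal convoluted tubule, 1 intercalated, 0 loop of Henle and 0 fat tissue markers.

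The remaining cell type lists did not pass at 600 mg/kg: principal cells of the collecting duct (2 of 8 rose, median 0.136, adjusted p = 0.169), inner medulla (3 of 7 rose, 0.117, 0.0503), and podocytes (1 of 8 fell, 0.089, 0.591). Nor did T cells (1 of 7 rose and 1 fell, 0.091, 0.609) or fibroblasts with smooth muscle (2 of 7 rose and 2 fell, 0.163, 0.444). Adjusted over the list alone these counts were 3 rising for principal cells, 3 rising for inner medulla, 1 falling for podocytes, 1 and 1 for T cells and 3 rising with 2 falling for fibroblasts. Untested for want of members were red blood cell genes (all 3 fell, median -0.618; Hbb log2 -1.01), adrenal genes (median 0.384, 1 of 2 rose), neutrophil genes (median 0.39, 0 of 2 called) and the single B cell gene measured (0.378). The fall of the red blood cell gene Alas2 was lost without control 1, 2 or 3, low 2, high 1 or high 3 (highest adjusted p = 0.134). Hbb was kept whichever array was left out. In total 21 of 29 lists were called at 600 mg/kg, 16 up and 5 down, 14 of them also with slide as a block. At no dose did any list pass with an estimated correlation.

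**Figure D2:**
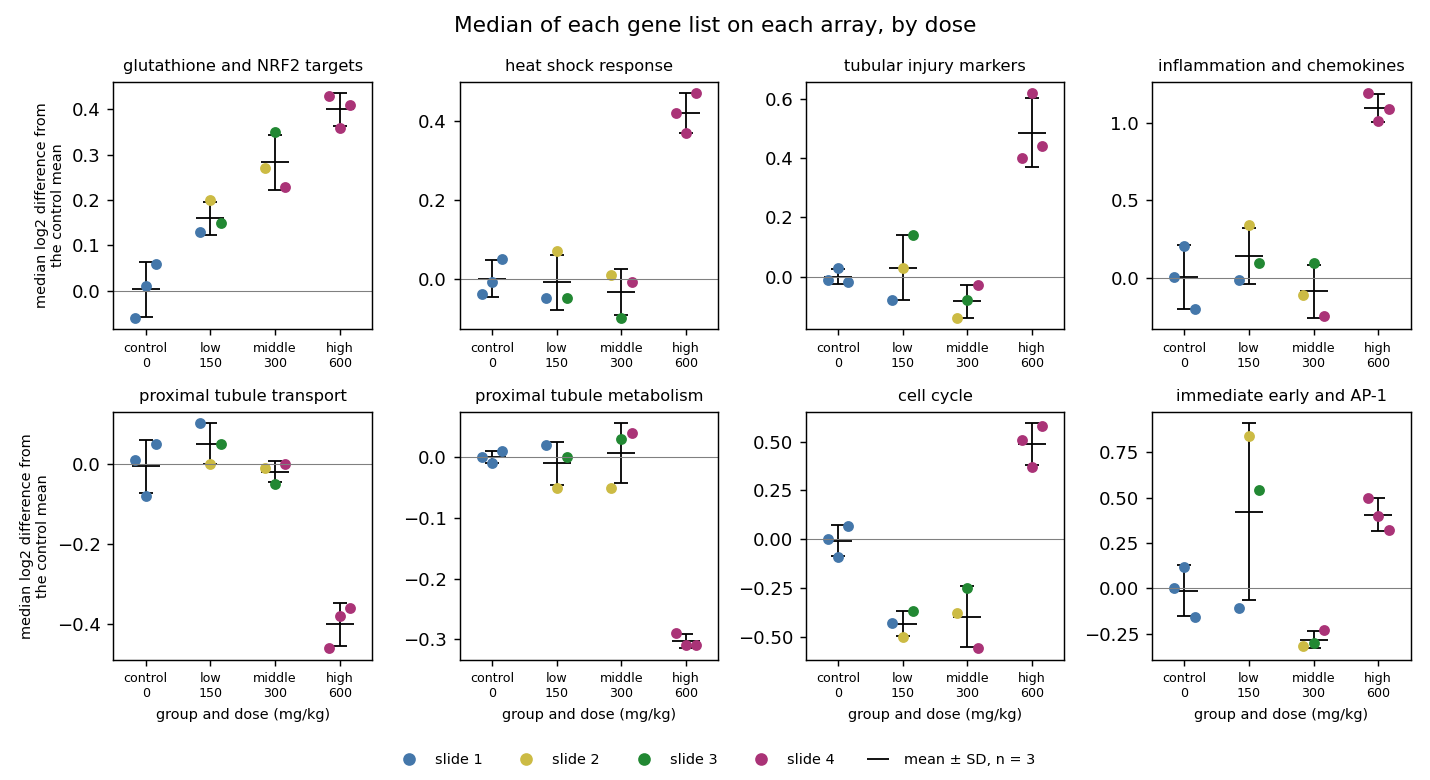
Median of 8 gene lists on each array over the mean of the controls (log2), by dose and coloured by slide. Cell cycle genes lay under the controls at 150 and 300 mg/kg and above them at 600 mg/kg.

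At 300 mg/kg Ugt2b7 rose 27.5-fold (log2 4.78 ± 0.21, n = 3 animals per group, adjusted p = 7.53e-06), the glutathione transferase gene Gstm1 4.99-fold (log2 2.32 ± 0.15, adjusted p = 6.05e-05) and Abcc2 4.32-fold (log2 2.11 ± 0.11, adjusted p = 2.63e-05). Apoa4 rose 2.85-fold (log2 1.51 ± 0.10, adjusted p = 6.05e-05), Nqo1 2.73-fold (log2 1.45 ± 0.09, adjusted p = 4.79e-05) and the muscle-type fructose bisphosphatase Fbp2 2.62-fold (log2 1.39 ± 0.08, adjusted p = 4.79e-05). Blocked by slide, these had adjusted p = 0.00835 for Ugt2b7, 0.0621 for Gstm1 (log2 2.21), 0.00797 for Abcc2, 0.00916 for Apoa4, 0.0316 for Nqo1 and 0.00835 for Fbp2. Also higher were the oxidoreductase-like Pir (2.61-fold, adjusted p = 5.71e-05; 0.0328 with slide as a block) and the membrane gene Ifitm6 (2.54-fold, adjusted p = 0.00124; 0.0178 with slide as a block). The heme synthesis gene Alas1 rose as well (2.1-fold, adjusted p = 5.66e-05; 0.0498 with slide as a block). A probe annotated to Atad1 rose 3.83-fold (adjusted p = 5.66e-05), but the gene's other probe moved by 0.04, so the annotation of the first is doubtful.

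Several genes changed at 600 mg/kg did not pass at 300 mg/kg: Hmox1 (log2 0.16, adjusted p = 0.383), Havcr1 (-0.27, 0.752), Timp1 (0.02, 0.868), Slc34a1 (-0.10, 0.174) and Slc22a6 (-0.06, 0.734). For Slc34a1 the other probe passed in the opposite direction (0.38, adjusted p = 0.00846). The tubular injury marker Gpnmb did rise, 2.1-fold (adjusted p = 0.00124; log2 0.78, adjusted p = 0.108 with slide as a block). The spindle midzone gene Prc1 fell (2.15-fold, log2 -1.11 ± 0.10, adjusted p = 0.000539; log2 -1.01, adjusted p = 0.0705 with slide as a block). The kinetochore genes Knstrn (2.21-fold, log2 -1.15 ± 0.11, adjusted p = 0.000866; log2 -1.10, adjusted p = 0.0844 blocked by slide) and Ska1 (2.09-fold, adjusted p = 0.00649; log2 -0.83, adjusted p = 0.185 blocked by slide) fell too, as did the mitotic cyclin Ccnb1 (1.92-fold, log2 -0.94 ± 0.11, adjusted p = 0.00191; log2 -0.84, adjusted p = 0.107 blocked by slide). Cyp2c11 fell 2.28-fold (log2 -1.19 ± 0.25, adjusted p = 0.0166), lost without control 2 (adjusted p = 0.0645) and, with a larger fall, with slide as a block (log2 -1.93, adjusted p = 0.0677). Cyp24a1 fell by 1.82 (standard error 0.46, adjusted p = 0.031), lost without control 1, control 2 or middle 3 (highest adjusted p = 0.113) and with slide as a block (log2 -1.13, adjusted p = 0.385).

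At 300 mg/kg 2704 of 20760 genes were called (13%), 1705 higher and 999 lower, 58 of them at least 2-fold (36 and 22). The split depended on the scaling, with 2033 higher and 721 lower after a median shift and 2049 and 722 in the authors' value table. Without control 1 the count was 741 and without control 2 it was 710. With slide as a block 45 genes were called, 25 higher and 20 lower, 25 of them in both fits, and the groups did not overlap in 32.7% of genes, where chance gives 10%.

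Among the lists at 300 mg/kg, NRF2 targets rose in 16 of 27 with 0 falling (19 and 0 adjusted over the list alone), with a median of 0.28 (camera, adjusted p = 2.76e-09, adjusted p = 0.163 with an estimated correlation, 8.31e-06 with slide as a block). Srxn1, Ugt1a6 and Gstp1 rose beside Gstm1 and Nqo1 (2.11-, 2- and 1.96-fold; adjusted p = 0.00468, 0.00231 and 0.00112), none of these 3 past with slide as a block, though about as large there (log2 1.04, 1.06 and 0.88, adjusted p = 0.171, 0.113 and 0.108). Cell cycle genes fell in 18 of 37 and rose in 4 (20 and 6 adjusted over the list alone), with a median of -0.402 (adjusted p = 4.09e-06, adjusted p = 0.52 with an estimated correlation, 0.000206 with slide as a block). The 4 that rose were Cdc6, Mcm3, Mcm2 and Mcm6. Ribosomal protein genes rose in 15 of 36 (25 adjusted over the list alone, median 0.179, adjusted p = 7.4e-09, adjusted p = 0.52 with an estimated correlation, 1.31e-05 with slide as a block). Endothelial markers fell in 3 of 12 (10 adjusted over the list alone, median -0.297, adjusted p = 1.31e-05, adjusted p = 0.313 with an estimated correlation, 0.00025 with slide as a block). Intercalated cell markers rose in 4 of 8 (6 adjusted over the list alone, median 0.304, adjusted p = 0.000748, adjusted p = 0.52 with an estimated correlation, 1.89e-05 with slide as a block). Those of the distal convoluted tubule rose in 3 of 5 (5 adjusted over the list alone, median 0.31, adjusted p = 0.0051, adjusted p = 0.52 with an estimated correlation, 0.000262 with slide as a block). Slide as a block called 1 NRF2 target and 0 members of the cell cycle, ribosomal, endothelial, intercalated and distal convoluted tubule lists. Its medians were 0.278, -0.294, 0.169, -0.248, 0.506 and 0.497 for these 6 lists, so the change was not removed with the calls.

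Weaker calls at 300 mg/kg took in cholesterol synthesis genes, of which 7 of 24 rose (8 adjusted over the list alone, median 0.192, adjusted p = 0.00105, adjusted p = 0.52 with an estimated correlation, 0.482 with slide as a block). Immediate early genes fell in 3 of 23 (3 adjusted over the list alone, median -0.318, adjusted p = 0.00161, adjusted p = 0.579 with an estimated correlation). The median of the immediate early genes was -1.215 with slide as a block (adjusted p = 7.59e-20). That blocked value runs through low 2 and low 3, which stood apart (0.84 and 0.54 over the controls, against -0.11 for low 1). The middle animals themselves lay at -0.32, -0.3 and -0.23, so -1.215 is not the size of a fall at 300 mg/kg. Genes of matrix and tissue repair fell in 2 of 28 (1 adjusted over the list alone, median -0.106, adjusted p = 0.0104, adjusted p = 0.52 with an estimated correlation, 4.25e-05 with slide as a block). That was lost without middle 2 (adjusted p = 0.0666). Genes of the proteasome rose in 4 of 27 (4 adjusted over the list alone, median 0.088, adjusted p = 0.0051, adjusted p = 0.579 with an estimated correlation, 0.0497 with slide as a block). That was lost without middle 2 (adjusted p = 0.0751) and under quantile normalization (median 0.022, adjusted p = 0.351). The reference genes rose in 5 of 12 (5 adjusted over the list alone, median 0.084, adjusted p = 0.0271, adjusted p = 0.52 with an estimated correlation, 0.0542 with slide as a block). That too was lost under quantile normalization (adjusted p = 0.0791). Slide as a block called 0 cholesterol, 0 proteasome and 0 reference genes, 1 matrix gene lower and 5 immediate early genes lower.

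Not past at 300 mg/kg were tubular injury markers (2 of 23 rose and 1 fell, median -0.093, adjusted p = 0.135; down with 0.000563 with slide as a block). Nor was inflammation (2 of 29 fell, -0.127, 0.237; down with a median of -0.489 and 0.000563 with slide as a block). The same held for heat shock genes (1 of 16 fell, -0.035, 0.397), proximal tubule metabolism (4 of 35 fell, -0.025, 0.177) and proximal tubule transport (3 of 34 rose, adjusted p = 0.654). In that last list the median of -0.056 and the mean of 0.041 differed in sign. The blocked median of inflammation runs through low 2 and low 3 (0.34 and 0.1 over the controls, against -0.01 for low 1). ER stress genes (-0.069, 0.358), p53 targets (0.052, 0.523), fatty acid oxidation (0.027, 0.639), oxidative phosphorylation (0.051, 0.152) and metal handling (0.047, 0.274) did not pass either. Fatty acid oxidation and oxidative phosphorylation, blocked by slide, had adjusted p = 0.00189 and 0.000563, both up, and ER stress 0.0172, down. No other cell type list passed: loop of Henle 0.135, principal cells 0.113, inner medulla 0.507, podocytes 0.231, macrophages 0.0871, T cells 0.745 (median 0.006, mean -0.011), fibroblasts 0.113 and fat 0.639. Untested red blood cell genes had a median of -0.639, neutrophil genes -0.745, adrenal genes 0.395 and the B cell gene 0.167. In total 11 lists were called, 7 up and 4 down, 9 of them also with slide as a block.

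At 150 mg/kg few genes passed. Ugt2b7 rose 9.19-fold (log2 3.20 ± 0.21, n = 3 animals per group, adjusted p = 0.000406; 0.0247 with slide as a block). Gstm1 rose 3.89-fold (log2 1.96 ± 0.15, adjusted p = 0.00152; log2 1.85, adjusted p = 0.101 with slide as a block) and Alas1 1.59-fold (log2 0.67 ± 0.07, adjusted p = 0.00753; log2 0.56, adjusted p = 0.167 with slide as a block). The doubtful Atad1 probe rose 2.73-fold (log2 1.45 ± 0.12, adjusted p = 0.0019; log2 1.36, adjusted p = 0.14 with slide as a block), against 0.06 for the gene's other probe. Among the named genes these 4 alone kept their call whichever array was left out. With only the compared groups in the fit, 0 of the 16 named genes called at this dose were kept, so these 4 were lost as well. Ugt1a6 (2.03-fold, adjusted p = 0.015) was lost without control 1, control 2, low 2 or low 3 (highest adjusted p = 0.127), and Pir (1.79-fold, 0.00948) and Gstp1 (1.78-fold, 0.015) without low 2 or low 3 (highest adjusted p = 0.0546 and 0.107). The peroxisomal thiolase Acaa1b (1.52-fold, 0.015, 0.0247 with slide as a block) was lost without control 1 or control 2 (highest adjusted p = 0.127). Nqo1 was called higher too, but was lost without control 1, 2 or 3, low 2 or 3, middle 2, or high 1, 2 or 3 (highest adjusted p = 0.239). Blocking by slide gave Ugt1a6, Pir and Gstp1 changes about as large (log2 1.09, 0.82 and 0.82) with adjusted p = 0.167, 0.146 and 0.196.

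Lower at 150 mg/kg was the mitotic cyclin Ccnb1 (1.7-fold, log2 -0.76 ± 0.11, adjusted p = 0.0343; log2 -0.77, adjusted p = 0.192 with slide as a block). It was lost without control 1, 2 or 3, low 1, 2 or 3, middle 1, or high 1, 2 or 3 (highest adjusted p = 0.196). Prc1 fell by 0.74 (adjusted p = 0.0343; log2 -0.72, adjusted p = 0.168 with slide as a block) and was lost without control 1, 2 or 3, low 2 or 3, or high 1 or 3 (highest adjusted p = 0.196). Hmox1 (log2 0.11, adjusted p = 0.806), Havcr1 (0.34, 0.868) and Slc34a1 (0.00, 0.987) did not pass.

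In all 21 of 20760 genes were called at 150 mg/kg (0.1%), 12 higher and 9 lower, of which 4 rose at least 2-fold and 0 fell so far. Leaving out a single array moved that count: control 1 to 6, control 2 to 10, low 1 to 46, low 2 to 5, low 3 to 7, middle 1 to 12, middle 3 to 35, high 1 to 8, high 2 to 12 and high 3 to 9. Only 7 were called with slide as a block, all higher, 3 of them in both fits. Groups did not overlap in 19.8% of genes, where chance gives 10%.

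Among the lists at 150 mg/kg cell cycle genes fell in 2 of 37 (22 adjusted over the list alone), with a median of -0.429 (camera, adjusted p = 9.73e-22, adjusted p = 0.356 with an estimated correlation, 4.79e-20 with slide as a block). NRF2 targets rose in 4 of 27 (12 adjusted over the list alone), with a median of 0.138 (adjusted p = 6.97e-12, adjusted p = 0.088 with an estimated correlation, 4.87e-07 with slide as a block). Endothelial markers had a lower median of -0.106 with 0 of 12 called (0 adjusted over the list alone, adjusted p = 0.00876, adjusted p = 0.574 with an estimated correlation, 0.029 with slide as a block). Intercalated cell markers had a higher one of 0.161 with 0 of 8 called (0 adjusted over the list alone, adjusted p = 0.00876, adjusted p = 0.574 with an estimated correlation, 2.19e-05 with slide as a block). The intercalated call was lost without control 1 (adjusted p = 0.0572) or low 1 (adjusted p = 0.211). Slide as a block called 0 members of these 4 lists.

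Immediate early genes had a median of 0.452, or 0.349 with bounds, at 150 mg/kg with 0 of 23 called (0 adjusted over the list alone, adjusted p = 7.75e-05, adjusted p = 0.574 with an estimated correlation). The list turned down with slide as a block, with a median of -0.112 (adjusted p = 0.001). Inflammation genes had a median of 0.158, or 0.155 with bounds, with 0 of 29 called (4 adjusted over the list alone, adjusted p = 0.00879, adjusted p = 0.59 with an estimated correlation, 0.705 with slide as a block). That call was lost without control 3 (adjusted p = 0.263) or low 2 (adjusted p = 0.109). The reference genes stood at 0.073 with 0 of 12 called (0 adjusted over the list alone, adjusted p = 0.0492, adjusted p = 0.574 with an estimated correlation, 0.0534 with slide as a block). That last list was lost without control 1 (adjusted p = 0.09), control 2 (0.108), low 1 (0.0913), low 3 (0.117), middle 1 (0.0522), high 1 (0.0604), high 2 (0.0526) or high 3 (0.0535). It was also lost under quantile normalization (0.0675), a median shift (0.0601), the authors' value table (0.0608) and the replicate block (0.0691). In total 7 lists were called, 5 up and 2 down, 4 of them also with slide as a block.

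The other lists did not pass at 150 mg/kg without a block, with 0 members called in each. Medians and adjusted p were 0.043 and 0.698 for tubular injury, 0.017 and 0.217 for proximal tubule transport, -0.015 and 0.72 for proximal tubule metabolism, 0.009 and 0.447 for fatty acid oxidation, 0.029 and 0.16 for oxidative phosphorylation, and 0.074 and 0.16 for p53 targets. Cholesterol synthesis stood at 0.064 and 0.211, metal handling at 0.073 and 0.0617, the proteasome at 0.023 and 0.4 and ribosomal proteins at 0.032 and 0.16. Signs differed for heat shock genes (median -0.014, mean 0.013, 0.698), ER stress genes (median 0.003, direction down, 0.698) and matrix genes (median 0.026, direction down, 0.869). Cell type lists gave 0.16 for loop of Henle, 0.0674 for distal convoluted tubule, 0.16 for principal cells, 0.379 for inner medulla, 0.208 for podocytes, 0.177 for macrophages, 0.4 for T cells, 0.15 for fibroblasts and 0.72 for fat. Blocking by slide, which here rests on low 1, 9 of these lists passed. Higher were fatty acid oxidation (adjusted p = 0.00013), oxidative phosphorylation (0.000844), distal convoluted tubule (0.00219), metal handling (0.00426) and proximal tubule transport (0.029). Lower were tubular injury (0.0289), ER stress (0.0289), matrix genes (0.0307) and fibroblasts (0.0307). Untested lists had medians of -0.135 for neutrophils, -0.044 for the B cell gene, 0.089 for red blood cells and 0.183 for the adrenal gland.

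Between 300 and 600 mg/kg genes of heat shock and tubular injury rose. Hspa1a rose 49.7-fold (log2 5.64 ± 0.28, n = 3 per group, adjusted p = 4.14e-06; 0.00011 with slide as a block), Hmox1 10.2-fold (log2 3.35 ± 0.11, adjusted p = 7.66e-07; 0.000357 blocked by slide) and Havcr1 11-fold (log2 3.46 ± 0.51, adjusted p = 0.00127; 0.0226 blocked by slide). Cyp24a1 rose 12.9-fold (adjusted p = 0.000555; log2 4.83, adjusted p = 0.00332 with slide as a block) and Cdc6 3.76-fold (adjusted p = 1.11e-06; 0.000357 blocked by slide). The proliferation antigen Mki67, lower at 300 mg/kg, rose 2.3-fold (adjusted p = 0.000226; 0.00173 with slide as a block). G6pc1 fell 2.14-fold (log2 -1.10 ± 0.09, adjusted p = 5.13e-05; 0.00384 with slide as a block), the muscle kinase gene Mylk3 2.48-fold (adjusted p = 0.00051; 0.0305 blocked by slide), Slc34a1 by 0.49 (adjusted p = 0.000132; 0.00615 blocked by slide) and Slc22a2 by 0.39 (adjusted p = 0.0084; 0.0101 blocked by slide). In all 4665 of 20760 genes were called, 1995 higher and 2670 lower, 261 of them at least 2-fold (237 and 24). Of these, 1678 were also called with slide as a block, which here rests on middle 3 and called 2024 genes.

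Cell cycle genes rose in 34 of 37 between these doses (35 adjusted over the list alone, median 0.846, adjusted p = 7.11e-30, adjusted p = 0.0855 with an estimated correlation). Inflammation genes rose in 24 of 29 (24 adjusted over the list alone, median 1.16, adjusted p = 8.37e-13, adjusted p = 0.136 with an estimated correlation). Tubular injury markers rose in 15 of 23 (18 adjusted over the list alone, median 0.536, adjusted p = 1.49e-12, adjusted p = 0.0719 with an estimated correlation). Heat shock genes rose in 10 of 16 (10 adjusted over the list alone, median 0.338, adjusted p = 1.27e-11, adjusted p = 0.0719 with an estimated correlation). Proximal tubule metabolism fell in 21 of 35 with 1 rising (23 and 1 adjusted over the list alone, median -0.293, adjusted p = 3.99e-09, adjusted p = 0.0719 with an estimated correlation). Transport fell in 20 of 34 with 1 rising (20 and 4 adjusted over the list alone, median -0.356, adjusted p = 2.2e-06, adjusted p = 0.136 with an estimated correlation). Fatty acid oxidation fell in 15 of 29 with 2 rising (17 and 2 adjusted over the list alone, median -0.229, adjusted p = 7.21e-05, adjusted p = 0.285 with an estimated correlation). In total 20 of 29 lists were called, 16 up and 4 down, and 15 of them, among them the 7 named here, also with slide as a block. Members called with slide as a block were 33 for the cell cycle, 20 for inflammation, 10 for tubular injury, 9 for heat shock, 18 lower for metabolism, 16 lower for transport and 9 lower for fatty acid oxidation.

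Between 150 and 300 mg/kg few genes passed. Abcc2 rose 2.82-fold (log2 1.49 ± 0.11, n = 3 per group, adjusted p = 0.000784; 0.00494 with slide as a block) and Apoa4 2.28-fold (log2 1.19 ± 0.10, adjusted p = 0.00151; 0.00662 blocked by slide). Ugt2b7 rose 3-fold (log2 1.58 ± 0.21, adjusted p = 0.0168; 0.0462 blocked by slide), Gpnmb 1.97-fold (adjusted p = 0.00765; 0.0388 blocked by slide) and Nqo1 1.82-fold (adjusted p = 0.00355; 0.032 blocked by slide). Mpv17l fell by 0.46 (adjusted p = 0.00448; 0.0462 with slide as a block). In all 48 genes were called, 40 higher and 8 lower, and 20 of these were kept with slide as a block. That fit called 71, with the balance turned to 31 higher and 40 lower, and with quantile scaling and slide as a block, tried after the data were seen, 25 were higher and 23 lower. The count without a block became 26 without control 1, 27 without control 2, 90 without low 1, 13 without low 2, 21 without low 3, 90 without middle 1, 12 without middle 2, 26 without high 1, 30 without high 2 and 23 without high 3. NRF2 targets rose in 2 of 27 (9 adjusted over the list alone, median 0.12, adjusted p = 0.000202, adjusted p = 0.456 with an estimated correlation, 0.00799 with slide as a block). Immediate early genes had a median of -0.608 with 0 of 23 called (14 lower adjusted over the list alone, adjusted p = 7.94e-15, adjusted p = 0.456 with an estimated correlation). That drop is largely low 2 and low 3, at 0.84 and 0.54 over the controls, against -0.11 for low 1 and -0.32, -0.30 and -0.23 for the middle animals. Ribosomal protein genes had a median of 0.157 with 0 of 36 called (17 higher adjusted over the list alone, adjusted p = 1.48e-11, adjusted p = 0.526 with an estimated correlation). In total 11 lists were called, 6 up and 5 down, 10 of them also with slide as a block.

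Across doses, genes called at 600 mg/kg and at 300 mg/kg mostly shared a direction: 1114 were higher in both, 680 lower in both, and 80 went opposite ways, Cyp24a1 among them. Both comparisons share the controls, which by itself brings such counts together, and the counts were not simulated. The changes at both doses correlated with r = 0.52 over all genes, against 0.5 in simulations that shared the controls and held no effect at any dose. Effects that differ between doses were not simulated, so the correlation itself says little for or against a shared response. Covariance was 0.046 against 0.0097, more than the noise of shared controls gave, though a slide difference from the controls could add to it. Of the 7224 genes called at 600 mg/kg 73.1% differed between 150 and 300 mg/kg in the direction of that call, a contrast that holds neither controls nor high-dose arrays. It is not free of slide, since low 1 lay on the slide of the controls and middle 3 on that of the high animals. A difference between those slides could raise the share. The highest other split gave 67.6% (exact p = 0.1, the smallest possible, 10 splits, counted in either direction), and the share was 62% within slide 2, 62.4% within slide 3 and 64.9% over both. The median standard deviation between animals was 0.07 in the high group, 0.066 in controls, 0.073 at 150 mg/kg and 0.11 at 300 mg/kg. For high against control the ratio was 1.063 (two-sided exact p = 0.4), and with 10 splits no p under 0.1 was possible, so a difference could not have passed.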

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

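The calls rest on 3 animals per group, on slides that nearly follow the groups and on a preset correlation for lists, and no choice removes these limits. Replicate numbers did not pair the arrays: of 18 same-number pairs 1 correlated above 0.1 (r from -0.23 to 0.12), and 2 of 12 arrays matched their own number best. The replicate block called 9 genes at 150 mg/kg and 18 from 150 to 300 mg/kg. Settings made after seeing the data were the slide block with a 2-fold limit, quantile scaling with the slide block, slides 2 and 3 alone, and the correlation under each setting. Where a value moved or turned, the cause was not tested.

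With slide as a block 584, 45 and 7 genes were called at 600, 300 and 150 mg/kg and 2024 from 300 to 600 mg/kg. Lists at 150 mg/kg numbered 14, the same-sign share was 92.3% (64.9% on slides 2 and 3 alone) and the correlation 0.691. In that fit the change at 600 mg/kg is chained through the middle minus low difference, so the 92.3% is partly built in. The blocked changes at 600 and 300 mg/kg share links of that chain. No correlation without an effect was simulated for them, so 0.691 says little. Changes at 600 mg/kg turned for Gdf15 (-0.27), Cdkn1a (-0.05), Cidec (-0.12) and Lrp2 (0.04). The low animals, which enter that chain, differed for Gdf15 (log2 signal 0.57 on low 1, against 1.76 and 1.81 on low 2 and low 3) and for Cdkn1a (-0.9, against -0.22 and -0.15). A 2-fold limit on top left 281, 31, 5, 300 and 25 genes for the 5 comparisons (600, 300 and 150 mg/kg against control, 300 to 600, 150 to 300 mg/kg). Quantile scaling with slide as a block gave 624, 38, 8 and, from 300 to 600 mg/kg, 2161. Scan day as a block gave 8 genes at 150 mg/kg, 31 from 150 to 300 mg/kg and a correlation of 0.498.

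A 2-fold limit without a block left 352, 58, 4, 261 and 5 genes. Only the compared groups in the fit gave 264 at 300 mg/kg, 0 at 150 mg/kg, 2540 from 300 to 600 mg/kg and 0 from 150 to 300 mg/kg. From 150 to 300 mg/kg a median shift gave 28 genes, and 29 were called in the authors' value table. Normexp gave 42 at 150 mg/kg. Without a filter on dim probes the counts were 897, 12, 3024 and 14 (300 and 150 mg/kg, 300 to 600, 150 to 300 mg/kg), with a spread ratio of 1.47. Probes well above background on all arrays gave a correlation of 0.549. Trended and robust moderation gave 42 at 150 mg/kg and 107 from 150 to 300 mg/kg, and array weights 133 and 11, with 11 lists at 150 mg/kg. With an estimated correlation 0, 0 and 0 lists passed with camera at 600, 300 and 150 mg/kg.

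With every probe on its own, another probe of the gene turned at 600 mg/kg for Atad1 (-0.07), Calb1 (-0.08), Mdm2 (0.39, adjusted p = 0.00252) and Txnrd1 (-0.41). At 300 mg/kg this held for Slc34a1 (0.38, adjusted p = 0.00846). The mean of the probes gave 0.18 for Mdm2 (adjusted p = 0.0204). Leaving out an array moved genes called at 300 mg/kg from 710 (control 2) to 2716 (middle 1), at 150 mg/kg from 5 (low 2) to 46 (low 1), and from 150 to 300 mg/kg from 12 (middle 2) to 90 (low 1). The same-sign share ran from 68 (low 1) to 76% (control 3), the correlation from 0.468 (middle 3) to 0.557 (control 3) and the spread ratio from 0.847 (high 1) to 1.457 (control 3).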

Other observations

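Gene families were picked after the values were seen, and no test compared one family with another. Glucuronosyltransferases rose at every dose: 3 of 8 at 150 mg/kg (median 0.58, adjusted p = 2.71e-10), 5 at 300 mg/kg (median 1.02, adjusted p = 9.83e-06) and 7 at 600 mg/kg (median 0.90, adjusted p = 7.83e-05), with 0 falling. With an estimated correlation the family passed at 150 mg/kg alone (adjusted p = 0.00949, against 0.0575 and 0.0923). Glutathione S-transferases rose in 2 of 21 at 150 mg/kg (adjusted p = 1.26e-08; adjusted p = 0.0511 with an estimated correlation) and 11 at 300 mg/kg (adjusted p = 2.57e-05; adjusted p = 0.169 with an estimated correlation). At 600 mg/kg 7 rose, led by Gstm1 and Gstp1, while Mgst3, Gstt2 and Gsta4 fell, and the family did not pass (adjusted p = 0.128).

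Cytochromes P450 split at 600 mg/kg, with 7 of 34 higher (Cyp24a1, Cyp1b1, Cyp7b1 among them) and 10 lower (Cyp2c11, Cyp2e1, Cyp2c23), and the family did not pass (adjusted p = 0.805). Solute carriers did the same, with 54 of 262 higher and 63 lower (adjusted p = 0.805), as did ABC transporters, with Abcc2, Abcb1b and Abcc3 among the 4 of 36 higher and 8 lower (adjusted p = 0.837). Solute carriers passed upward at 150 mg/kg, with 0 members called (adjusted p = 0.0204; adjusted p = 0.259 with an estimated correlation; 0.148 with slide as a block), and not at 300 mg/kg, with 27 higher and 5 lower (adjusted p = 0.205). At 300 mg/kg aldo-keto reductases passed upward, 3 of 14 rising (adjusted p = 0.043; adjusted p = 0.377 with an estimated correlation; 0.169 with slide as a block), and histones downward, 1 of 21 falling (adjusted p = 0.043; adjusted p = 0.443 with an estimated correlation; 0.153 with slide as a block). Claudins rose in 3 of 15 at 600 mg/kg (Cldn14, Cldn4 and Cldn8, adjusted p = 0.361), and of the 10 aquaporins Aqp8 rose and Aqp1 fell (adjusted p = 0.837).

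The tests of slide for small changes were chosen only after the result was seen, while regrouping the arrays was planned before. Slide as the whole cause of the many small changes at 600 mg/kg was not excluded. Of 6872 genes under 2-fold, 61.9% and 62.3% kept their direction between middle and low animals within slides 2 and 3. Both lay inside the 13.5 points by which single pairs of animals of 1 group strayed at most from 50%. The low group, on 3 slides, had a median standard deviation of 0.073, against 0.066 for controls on 1 slide. The middle group, also on 3 slides, had 0.11. With group means removed, the low and middle arrays that shared slide 2 or slide 3 correlated at -0.04 and 0.08. These values show little slide effect in the low group and do not settle the question. Slide as part of the cause might also hold, since 59.3% of genes called at 300 mg/kg moved the same way between low 2 and 3 and low 1 (55.9% and 35.8% for the other choices), although low 1 may simply be a different animal. The fit with slide as a block shares arrays with the calls, so the 398 genes called in both do not settle it. Regrouping into 3 and 3 left 1 of 10 splits with as many genes at each dose and between neighbouring doses, and a share that cannot go under 0.1: 7224 against at most 0, 2704 against 2, 21 against 1, 4665 against 0 and 48 against 9. For lists the number of splits was 1 at 600 mg/kg (21 against at most 17), 3 at 300 mg/kg (11 against 15) and 5 at 150 mg/kg (7 against 15). Each other split still sets doses 2 against 1, and with an estimated correlation 0 lists passed, so what lies behind the list counts stays open.

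The test of a single animal for cell cycle genes was planned, while those of slide and of mitosis against replication were chosen only after the result was seen. Genes of the cell cycle lay lower at 150 and 300 mg/kg and higher at 600 mg/kg, and a single animal was argued against: with 1 array left out the median closest to 0 was -0.39, -0.31 and 0.45 at these doses. The levels on each array argue against slide as the whole cause. They were -0.43, -0.5 and -0.37 for low 1 to 3 on slides 1 to 3 and -0.38, -0.25 and -0.56 for middle 1 to 3 on slides 2 to 4. Controls on slide 1 lay at 0, -0.09 and 0.07, and high animals on slide 4 at 0.51, 0.37 and 0.58. The median was -0.43 within slide 1 (controls differed by up to 0.13) and 1.06 within slide 4 (0.93 to 1.14). Each of these 2 rests on 1 library, low 1 or middle 3, so slide could still take part. A split within the list may describe it better: the 13 replication members stood 0.5 above the 24 mitosis members at 150 mg/kg and 0.82 above at 300 mg/kg (medians -0.08 and -0.58, then 0.21 and -0.61). At 600 mg/kg replication reached 1.16 and mitosis 0.19, and whether fewer cells divided or the same cells were held before mitosis stays open.

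The test of slide for immediate early genes was chosen only after the result was seen. These genes, which answer to handling and anaesthesia within minutes, differed between animals of the low dose, with medians over control of -0.11, 0.84 and 0.54 for low 1 to 3. Slide was argued against, since the middle animals on the slides of low 2 and low 3 lay 1.02 and 0.91 lower (closest -0.91 on slide 3), at -0.32 and -0.30. The list's turn to -0.112 with slide as a block rests on low 1 alone. A difference in handling or time of death was not tested, and what lies behind low 2 and low 3 stays open.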
